A study of Mus musculus with 3 samples.

How the data were processed

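Single-cell RNA sequencing was done on the epididymis of 56-day-old wild-type C57BL/6 mice, divided into caput, corpus and cauda with 1 library each (Singleron GEXSCOPE kit). The tissue was digested to single cells, passed through a strainer and treated to lyse red blood cells, and the libraries were read on a HiSeq X10, per the labels. Per the submitters' processing notes, reads were aligned to the mouse genome GRCm38.p6 with STAR 2.7.3a and unique molecular identifiers were counted with UMI-tools, whose version is not given in the sources used here. The deposited matrix holds UMI counts of 24335 gene symbols in 14845 cells. All values are whole, the largest is 3993, and each column names its region. How cells were told from empty wells is not given in the sources used here, and the reads were not used here. Gene positions are those of GENCODE M21 on GRCm38. Of the symbols, 16892 (69.4%) had a match, and 7143 symbols are names of genomic clones.

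Cells with fewer than 200 detected genes were left out (22 caput, 128 corpus and 140 cauda cells), with no ceiling on the mitochondrial share. Scrublet, run per library in scanpy 1.11.5, called no doublet in any library at its own thresholds of 0.453, 0.454 and 0.444, so no cell was left out as a doublet, and how many doublets remain was not measured. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours were taken, and the 3 libraries were clustered together with the Leiden method at resolution 1.0 (igraph 0.11.9, seed 0), with no correction between libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, and R 4.3.3 with edgeR 4.0.16 gave the TMM factors.

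Clusters took the names of 21 possible classes from marker lists (197 genes, of which 189 were in the matrix). A cluster was named where its 10 leading genes (highest ratio to all other cells among genes seen in at least 25% of its cells, with 0.01 added to each mean per 10000) held at least 2 markers of a class, more than of any other, and otherwise by the class with the highest share of its markers enriched. Either way at least 3 markers had to be enriched at least 2-fold and seen in at least 10% of the cells. A cluster with ribosomal RNA among the leading genes was left without a name. A cluster not named by its leading genes was also left without one where these held more markers of another class, or where a second class had at least 50% of its own markers enriched, and this second condition was not applied to clusters named by their leading genes, such as cluster 29, named lymphatic endothelial-like with all 12 endothelial markers enriched, and cluster 8, named endothelial-like with 6 of 8 pericyte markers enriched. The marker lists were set before the data were examined, as were the gene lists, the size rule, the rule for naming genes and most of the alternatives, while the thresholds of this naming rule were set after exploratory clusterings had been seen. Names are written with "-like" because they rest on markers alone. Principal-marker clusters are those in which principal markers came first, cluster 23 included. Clusters without a class held 8.67% of caput, 4.47% of corpus and 38.4% of cauda cells and were kept out of the region comparisons. After the data were seen, clusters 5 and 9 were split at Leiden resolution 0.5.

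UMIs were summed per region and class and given as CPM (UMIs scaled by the sum over all genes) with exact Poisson 95% intervals. The ratio of 2 regions had an interval from the exact conditional binomial, and shares had Clopper-Pearson intervals. Each region had 1 library and cells are not replicates, so no test was made. Caput was compared with corpus, caput with cauda and corpus with cauda, in the principal-marker clusters and in each other named class with at least 50 cells in both regions. A gene passed the size rule where the ratio was at least 4, its interval excluded 2, and the higher region had at least 100 UMIs in the class. A count of 0 was set to 3 over the region and the ratio written as "at least". Such a value is the ratio at that floor, and the lower limit of its interval can lie below it. Named genes were, among those past the size rule with a CPM in the class no lower than in all other cells of the higher region, the 10 with the largest ratio in each direction for principal-marker clusters and the 5 for other classes. Up to 4 members of each gene list, in order of summed UMIs, served as examples, along with the cell type markers. The level of 1 such example is not reported here. The clustering was done on the same counts, so a gene that leads a cluster is not a separate result. Some named genes and list members, such as Lcn9, Cst11, Rnase10, Adam28, Spint4 and Defb21, were also principal cell markers used to name clusters.

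For each of 34 gene lists, the median log2 ratio was taken over members with at least 20 UMIs in both regions together, where there were at least 3, and placed among 10000 random lists of the same size drawn within 20 expression bins. A member is called higher in a region where its interval excludes a ratio of 1. The lists were beta-defensins, lipocalins, cystatins, the ribonuclease A family, the CRISP family, Kazal inhibitors, Kunitz and WAP inhibitors, serpins, ADAM proteases, glutathione and peroxide handling, glutathione S-transferases, gamma-glutamyl transferases, mitochondrially encoded proteins, the nuclear respiratory chain, the TCA cycle, glycolysis, fatty acid oxidation, cholesterol synthesis, steroid hormone action, proton and bicarbonate transport, ion and water channels, tight junctions, chaperones of the endoplasmic reticulum, N-glycosylation and secretion, ribosomal proteins, dissociation stress, the interferon response, antigen presentation, innate defence, segment transcription factors, sperm and germ cell transcripts, extracellular matrix, contractile genes and complement. Genes per cell were counted after thinning each cell to 1000 UMIs. Free RNA was followed through the 10 most abundant genes of caput principal-marker clusters that were no lower there than in all other caput cells, mitochondrial and ribosomal protein genes left out. Because this set held Itm2b and Tmsb4x, which many cell types express, the measure was repeated after the result was seen with the 7 members of listed secreted families.

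The size rule was tested on simulated data drawn from the summed counts, with 200 changed genes among 24335. The changed genes were taken only from those above a floor of expected UMIs in the smaller region, so weakly expressed genes were not covered. At true folds of 2, 4, 8 and 16 it called 0%, 56%, 100% and 100% of them for caput against corpus, with 0 unchanged genes called, and 96.05% of the intervals held the true ratio. These values carry counting error only and no variation between animals, so calls among unchanged genes could hardly arise. The alternatives tried were a minimum of 500 genes or 1000 UMIs per cell, a ceiling of 20% on the mitochondrial share, the 6% highest Scrublet scores left out, barcodes shared between libraries left out, Leiden resolutions 0.5 and 2.0, 4000 variable genes with 50 components, each library clustered on its own, seed 1, other scalings, the deepest cells left out, other thresholds of the size rule and other thinning depths.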

Results

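RNA was measured in single cells of the epididymis, the coiled duct in which sperm mature and are stored, from 56-day-old wild-type C57BL/6 mice. The organ was divided into caput (the head, next to the testis), corpus (the body) and cauda (the tail), and each region gave 1 library. The deposited matrix held 4961 caput, 4959 corpus and 4925 cauda cells, with total counts of 41500792, 21495211 and 18341476 unique molecular identifiers (UMIs). After cells with fewer than 200 detected genes were left out, 4939, 4831 and 4785 cells remained, with medians of 5077, 2654 and 2198 UMIs per cell and 1938, 1097 and 952 detected genes. Mitochondrially encoded transcripts made up over 20% of the UMIs in 3.38% of caput, 28.5% of corpus and 25.9% of cauda cells. With 1 library per region there was no replicate check and no test. All intervals are exact 95% intervals that cover counting error only, and a difference between regions is also a difference between 2 libraries.

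The first question was which cell types each region held. Of 30 clusters, 7 got no name by the rule and 6 of these were counted with no class, while cluster 23, which got none because S100a8, a listed neutrophil marker, was among its leading genes, was counted with the principal-marker clusters for its principal cell markers. Cluster 13, which had macrophage markers and got no name for the dendritic marker Cd209a among its leading genes, was not counted with the macrophage-like cells. Epithelial clusters carried markers of principal cells (the main secretory cells of the duct), clear-like cells (acid-secreting cells that express Foxi1 and Atp6v1b1) and basal-like cells (Krt5, Krt14 and Trp63). Principal-marker clusters, cluster 23 included, made up 50.4% of caput (48.9 to 51.8), 52.2% of corpus (50.8 to 53.7) and 17.7% of cauda cells (16.6 to 18.8). Clear-like cells made up 12.7%, 10.4% and 2.03% of the same libraries, in clusters 7, 28 and 24 respectively, and basal-like cells 14.2%, 3.68% and 1.57%, in cluster 5 for the caput and cluster 25 for the others. Fibroblast-like cells (Col1a1, Dcn and Pdgfra; clusters 19 and 20) made up 11.9% of corpus and 24.97% of cauda cells (23.8 to 26.2). Macrophage-like cells (C1qa, Csf1r and Adgre1) made up 4.35% of caput cells in cluster 10, and 5.59% of corpus and 9.22% of cauda cells in cluster 17, without the 3.75% of corpus and 4.201% of cauda cells in cluster 13. Erythroid-like cells, which remained after a lysis of red blood cells, made up 3.12%, 5.32% and 1.71%. T or NK-like cells made up 2.48% of corpus and 1.96% of cauda cells, endothelial-like cells 6.44% of caput cells, smooth muscle-like cells 1.296% of cauda cells, lymphatic endothelial-like cells 1.55% of corpus cells and germ cell-like cells, led by Prm1 and Prm2, 1.45% of corpus cells. Most clusters came from 1 library: 18 of 30 had at least 95% of their cells from 1 region, so such a cluster may be that library and not a cell type. The 6 clusters counted with no class held 8.67%, 4.47% and 38.4% of the cells of caput, corpus and cauda.

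**Figure D1:**
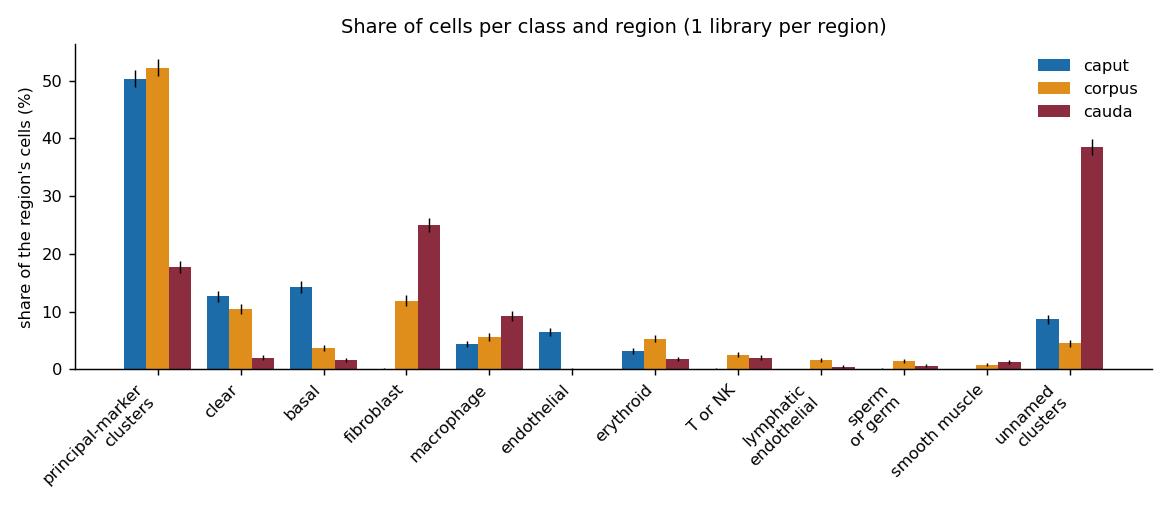
Share of each library's cells in the named classes and in the unnamed clusters, in percent, with exact 95% intervals (counting error only). Principal-marker clusters made up 50.4% of caput, 52.2% of corpus and 17.7% of cauda cells.

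Several of these shares depended on the clustering and give no direction between regions. The caput share of fibroblast-like cells was 0.0607% but lay between 4.902% and 5.93% in 9 of 11 alternatives. Cluster 9, an unnamed caput cluster of 370 cells, carried markers of both fibroblasts and smooth muscle. Split further, cluster 9 gave fibroblast-like groups of 25, 60 and 132 cells and smooth muscle-like groups of 31 and 75 cells, with a principal-like group of 26 cells and unnamed groups of 10 and 11 cells, and the fibroblast-like group of 60 cells held Gpx5 at 22551 CPM. Basal cluster 5 in the same way held a ciliated-like group of 102 cells, 2.07% of the caput, with Ccdc153 at 1165, Tmem212 at 1043 and Foxj1, the regulator of motile cilia, at 212 CPM. This split was chosen after the data were seen. A change of random seed alone gave a caput share of basal-like cells of 9.25%. That share ranged down to 8.79% and the corpus share of principal-marker clusters down to 30.8% when each library was clustered on its own. The cauda share of principal-marker clusters ranged up to 49.9% at Leiden resolution 0.5. The cauda share of fibroblast-like cells, 24.97%, was 25.1% with 4000 variable genes and 50 components but 50.1% at Leiden resolution 2.0. It was 53.9% with cells over 20% mitochondrial UMIs left out, which raises the other shares by construction. Unnamed cluster 22, nearly all from the cauda, had 10 of 13 listed fibroblast markers enriched. The cauda share of clear-like cells, 2.03%, was 0.0836% at Leiden resolution 2.0.

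Caput and corpus were compared first in the principal-marker clusters, the caput in clusters 0, 1, 3, 6 and 11 with 6 cells of cluster 12, and the corpus in clusters 12 and 26 with 9 cells of cluster 23. Spag11b, a defensin-like gene, was 5679.9-fold higher in the caput (4231 to 7817), at 20106 against 3.54 CPM. Genes of the cystatin family, named for inhibitors of cysteine proteases, were higher in the caput, with Cst11 6045-fold (3722 to 10576), Cst8 3842-fold (2582 to 5996) and Cst12, which had 3 corpus UMIs, 7136-fold (2442 to 34606). The lipocalins, carriers of small hydrophobic molecules, showed the same order, with Lcn9 5492-fold higher (3869 to 8084) and Lcn10, with 3 corpus UMIs, 5157-fold higher (1764 to 25006). Rnase10, of the ribonuclease A family, was 3978-fold higher in the caput (2163 to 8296), and Defb45, with 2 corpus UMIs, 5468-fold higher (1513 to 45149.5). In the corpus, the beta-defensin gene Defb22 was 9728-fold higher (4721 to 24199), at 2419.5 against 0.249 CPM, and Defb38 was 516-fold higher (437 to 614). Pate1 was 1858-fold higher in the corpus (1277 to 2820.4), Ltf, which encodes the iron-binding protein lactoferrin, 1295-fold (657 to 3002), Cwh43 789-fold (469.9 to 1445), Bsph2, of the binder of sperm family, 649.7-fold (506 to 849.7) and Erich6, with 1 caput UMI, 1024-fold (183 to 40514). The rule also named 5 clone-named transcripts, of which RP23-319C8.1 and RP23-250M11.8 were higher in the caput and RP23-146D13.2, RP23-138I21.5 and RP23-138I21.4 in the corpus.

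Several of these genes lie next to each other on chromosome 2 of GRCm38. The cystatin genes Cst11, Cst12 and Cst8 span 148768609 to 148805595, and the lipocalin genes Lcn5, Lcn6, Lcn10 and Lcn9 span 25657952 to 25825537, with the higher level in the caput for each. The beta-defensin genes Defb23, Defb22, Defb29, Defb21 and Defb45 lie between 152459055 and 152599399 and did not share a direction, since Defb22 was higher in the corpus and Defb45 in the caput. Members of these families are similar in sequence, and reads shared between copies would be counted as the upstream processing assigned them.

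Of 10435 genes with at least 100 UMIs in 1 of these regions, 732 passed the size rule higher in the caput and 437 higher in the corpus, against 376 and 282 after the sums were thinned to the total of the smallest region. Among the named genes, Cst12 also led cluster 0, Defb45 cluster 6, and Defb22, Bsph2, Pate1 and Defb38 cluster 26, so the clustering used them.

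**Figure D2:**
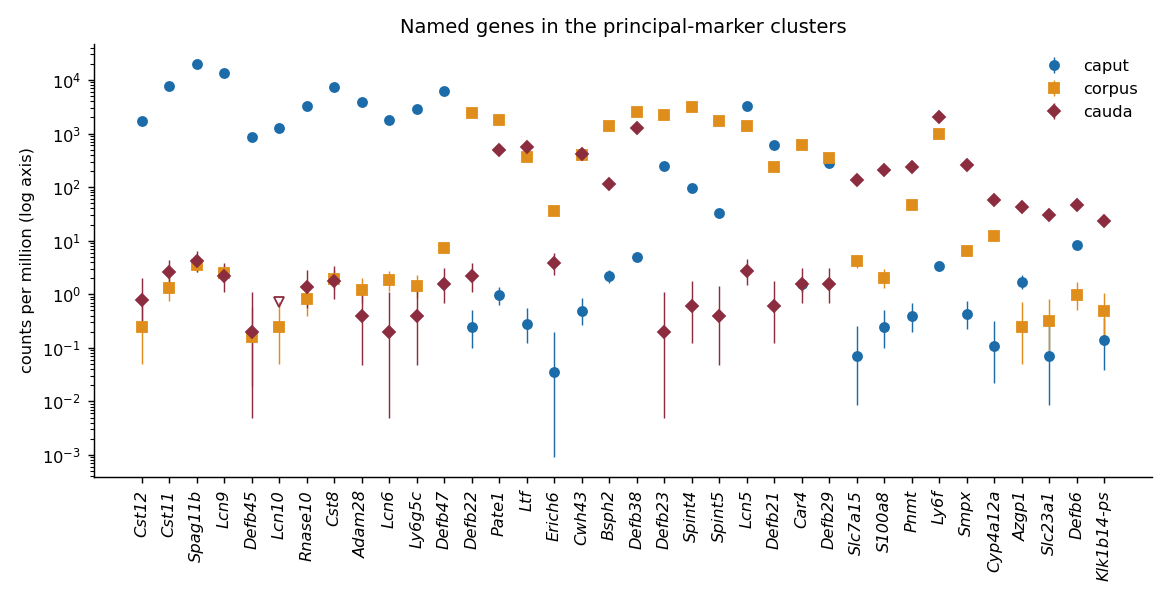
CPM (log axis) of the named genes, clone-named transcripts left out, in the principal-marker clusters of caput, corpus and cauda, with exact 95% Poisson intervals (counting error only). Genes with no UMI in a region are drawn at the upper limit of their interval. Spag11b lay at 20106 in the caput and at 3.54 and 4.15 in the corpus and cauda.

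Gene lists fixed in advance gave the wider view of caput against corpus. Each list's median log2 ratio is given with its percentile among 10000 random lists of matched expression. All 8 measured lipocalins (median 7.35, percentile 100) and all 7 cystatins (4.78, percentile 100) were higher in the caput, and Lcn8 stood at 12256 against 5.47 CPM. Of these lists, Lcn5, Lcn8, Lcn9, Lcn10, Lcn12, Cst8, Cst11 and Cst12 were also among the markers that named the principal-marker clusters. Of 22 transcription factors and signals that mark epididymal segments, 15 were higher in the caput and 6 in the corpus (2.30, percentile 100), with Sox9 at 163 against 22.4 and Etv5 at 79.4 against 1.13 CPM. Chaperones of the endoplasmic reticulum were higher in the caput for 18 of 19 members (0.63, percentile 99.93; Hspa5 2881 against 2181 CPM), as were 16 of 21 genes of N-glycosylation and secretion (0.40, percentile 97.9). Metabolic lists with a median above 0 were fatty acid oxidation (12 of 17 members higher in the caput; 0.62, percentile 99.6), the TCA cycle (13 of 17; 0.45, percentile 96.8) and cholesterol synthesis (10 of 19; 0.31, percentile 87.6). Genes of steroid hormone action had a median of 0.83 (percentile 98.8). The contractile list (0.96, percentile 99.8) held Actg2, at 1749 against 1.37 CPM. Proton and bicarbonate transport (0.39, percentile 96.8) went both ways, with Atp6v1a at 334 in the caput and 205 in the corpus, and Atp6v1g1 at 324 and 414 CPM. The ribonuclease A family (0.60, percentile 96.7), ADAM proteases (0.40, percentile 90.02) and the 3 measured gamma-glutamyl transferases (1.85, percentile 98.1) also had medians above 0.

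The corpus was higher for 11 of 18 glutathione S-transferases (-1.35, percentile 0), with Gstm7 at 1659 against 411 CPM, and for 13 of 21 Kunitz and WAP protease inhibitors (-0.52, percentile 0.405), with Wfdc13 at 7165 against 66.7 CPM. Kazal inhibitors had a median of 1.12 (percentile 99.7) while their most abundant member, Spink8, stood at 4448 in the caput and 20608 CPM in the corpus. Crisp1, whose product coats sperm, stood at 119 in the caput and 11050.2 CPM in the corpus, and its family had a median of -0.36 (percentile 19.9). Antigen presentation (-0.97, percentile 0.07), innate defence (-1.09, percentile 0.01), extracellular matrix (-1.35, percentile 0) and complement (-0.62, percentile 1.46) had medians below 0. The most abundant members of the innate defence and complement lists went the other way, with Lcn2 at 7474 in the caput and 274 CPM in the corpus and Clu at 4031 and 1233 CPM, so the innate defence list summed to 8217 and 1198 CPM and the complement list to 4189 and 1444 CPM. The matrix list stood at 1377 CPM in corpus principal-marker clusters and at 75897 CPM in fibroblast-like cells of that library, so RNA of these cells is not excluded. In corpus macrophage-like cells the antigen presentation and complement lists stood at 19036 and 6419 CPM, against 5399 and 1444 CPM in principal-marker clusters. For both, RNA of macrophage-like cells is not excluded either. All 9 measured sperm and germ cell transcripts were higher in the corpus (-3.94, percentile 0), summing to 169 CPM in a library in which germ cell-like cells made up 1.45% of cells. Nuclear genes of the respiratory chain (-0.20, percentile 0.62), ribosomal proteins (-0.18, percentile 5.21), glycolysis (-0.19, percentile 8.06), serpins (-0.13, percentile 22.9) and ion and water channels (-0.12, percentile 14.4) lay closer to 0. Medians whose sign turned under at least 1 other scaling were those of beta-defensins (0.14, percentile 84.5; 18 members higher in each region), glutathione and peroxide handling (0.04, percentile 46.6), tight junctions (0.10, percentile 54.7), dissociation stress (0.14, percentile 72.4) and the interferon response (-0.01, percentile 44.4). Within 1 of these lists the glutathione peroxidases stood apart: Gpx5 was at 40160.3 in the caput and 19.1 CPM in the corpus, and Gpx3 at 179 and 6046 CPM.

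**Figure D3:**
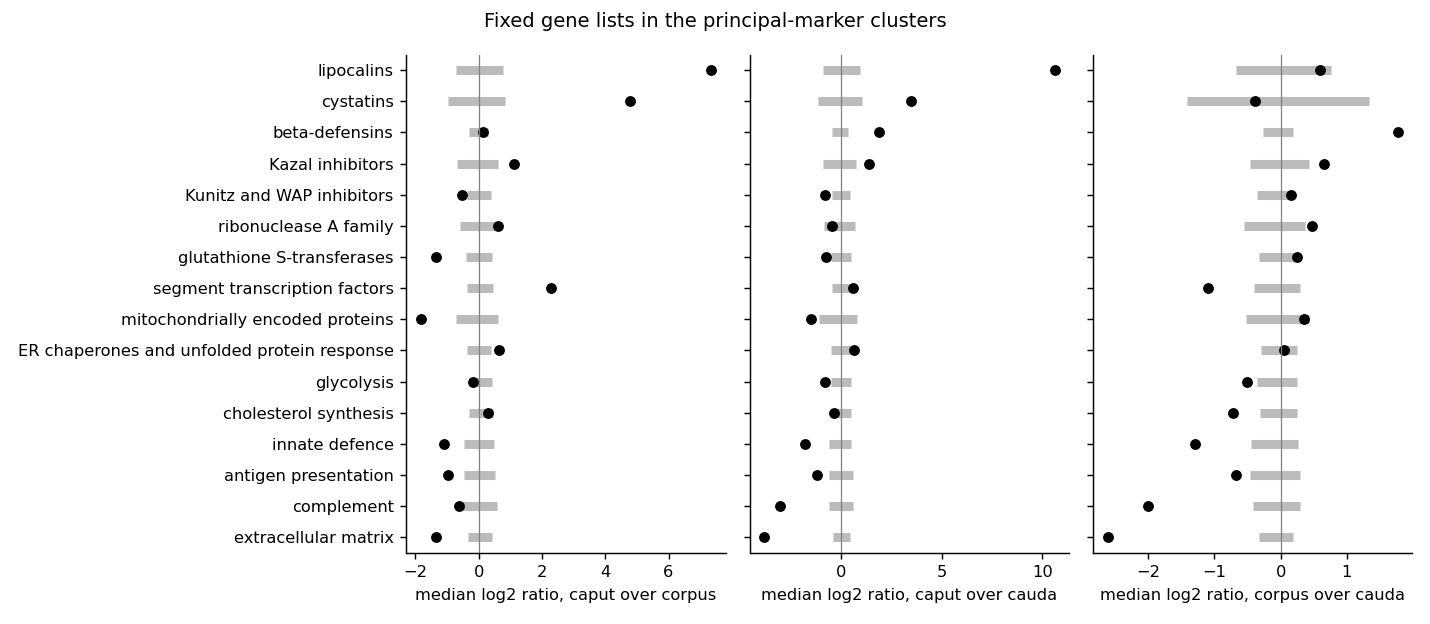
Median log2 ratio of a selection of the gene lists in the principal-marker clusters for caput over corpus, caput over cauda and corpus over cauda, each beside the central range of 10000 random lists of matched expression. The lipocalin median was 7.35 for caput over corpus and 10.61 for caput over cauda.

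Caput and cauda, the most distant regions of the duct, were compared with the caput in the same clusters and the cauda in cluster 23 with 22 cells of cluster 26. Adam28, of a family of membrane proteases, was 9709-fold higher in the caput, with 2 cauda UMIs (2688 to 80171), and Lcn6, with 1 cauda UMI, 9162-fold higher (1644 to 361883). Lcn9 was 6301-fold higher (3522 to 12623), Spag11b 4845-fold (3169 to 7827), Cst8 4171-fold (2197 to 9121) and Defb47 3856-fold (1957 to 8931). Ly6g5c, with 2 cauda UMIs, was 7116-fold higher in the caput (1969.8 to 58758) and Defb45, with 1 cauda UMI, 4452-fold (799 to 175842). In the cauda, Ltf was 1974-fold higher (1000.4 to 4576), at 561 against 0.284 CPM, and the amino acid transporter gene Slc7a15, with 2 caput UMIs, 1877-fold higher (518 to 15532). S100a8, a calcium-binding protein best known from neutrophils, was 829-fold higher in the cauda (401 to 2066), Pnmt, the enzyme that makes adrenaline from noradrenaline, 619-fold (345 to 1243) and Ly6f 606-fold (496 to 749), at 2068 CPM. Cwh43 was 839.9-fold higher (499 to 1539), Smpx 597-fold (340.3 to 1158) and Cyp4a12a, with 3 caput UMIs, 534-fold (181 to 2604). The clone-named AC148989.5 and RP23-319C8.1 were higher in the caput, and RP23-146D13.2 and 1 further clone-named transcript, with no caput UMI, in the cauda. The size rule passed 818 genes higher in the caput and 397 higher in the cauda of 10273, against 406 and 390 after thinning to equal totals. Adam28 also led cluster 0, Defb47 cluster 3, Defb45 cluster 6, and Slc7a15, Smpx, S100a8 and Pnmt cluster 23.

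Lipocalins had a median log2 ratio of 10.61 for caput over cauda and cystatins of 3.48, each at percentile 100. Of 35 beta-defensins, 22 were higher in the caput and 13 in the cauda (1.89, percentile 100), with Defb20 at 17637 against 17.4 CPM and Defb42 at 6089 against 322 CPM. Kazal inhibitors (1.40, percentile 99.8), chaperones of the endoplasmic reticulum (0.68, percentile 99.6) and segment transcription factors (0.60, percentile 99.2) also had medians above 0, although the Kazal inhibitors summed to 9139 CPM in the caput and 17850.2 CPM in the cauda. In the cauda, 9 of 18 serpins, inhibitors of serine proteases, were higher (-0.98, percentile 0.03), with Serpina1f at 2476 against 445 and Serpine2 at 911 against 12.4 CPM. Glycolysis was higher in the cauda for 14 of 18 genes (-0.78, percentile 0.17), with Ldhb at 904 against 375 CPM. Antigen presentation (-1.19, percentile 0.09; B2m 5459 against 1724 CPM), innate defence (-1.78, percentile 0) and Kunitz and WAP inhibitors (-0.79, percentile 0.1; Wfdc15b 8710.1 against 631 CPM) also had medians below 0. Extracellular matrix genes were higher in the cauda for 22 of 24 members (-3.80, percentile 0), as were 11 of 13 complement genes (-3.00, percentile 0), although the complement and innate defence lists summed to only 1763 and 1709.6 CPM in the cauda. The matrix list summed to 6985 CPM in the cauda principal-marker clusters, 8367 CPM in cauda macrophage-like cells and 132136 CPM in cauda fibroblast-like cells, and the complement list to 9272 CPM in cauda macrophage-like and 5529 CPM in cauda fibroblast-like cells, so for both lists RNA of these cells is not excluded. The antigen presentation list summed to 7202 CPM in cauda principal-marker clusters and 19541 CPM in cauda macrophage-like cells, so the same limit holds for it.

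Corpus and cauda differed in fewer genes, with 247 past the size rule higher in the corpus and 145 higher in the cauda of 7619. Defb23 was 11231-fold higher in the corpus, with 1 cauda UMI (2016 to 443632), and the protease inhibitor genes Spint4 and Spint5, with 3 cauda UMIs and 2 cauda UMIs, 5173-fold (1770 to 25086) and 4331-fold higher (1199 to 35764). Defb22 was 1113-fold higher (622 to 2229.9), Lcn5 508-fold (303 to 929), Defb29 218-fold (110.3 to 504) and Defb21, with 3 cauda UMIs, 405-fold (138 to 1963). Car4, a membrane-bound carbonic anhydrase, was 390-fold higher in the corpus (198 to 904), at 617 against 1.58 CPM, and stood at 1.53 CPM in the caput. In the cauda, Azgp1, with 3 corpus UMIs, was 179-fold higher (60.6 to 876), S100a8 102-fold (69.03 to 159), Defb6 48.9-fold (27.5 to 96.02) and Smpx 39.5-fold (31.5 to 50.2). Slc23a1, a transporter of vitamin C, was 93.3-fold higher in the cauda (35.7 to 347), at 30.04 against 0.322 CPM, and the pseudogene Klk1b14-ps 47.9-fold (21.4 to 133). The clone-named AC148989.5 and AC167121.2 were higher in the corpus, and RP23-38P5.10, RP23-265F16.1, RP23-34O23.4 and 1 further clone-named transcript in the cauda. At Leiden resolution 0.5, which put more cauda cells into principal-marker clusters, the counts past the size rule were 243 and 338, so which region held more of these genes was not settled, and thinning to equal totals gave 150 and 142. Spint4, Spint5, Defb23 and Defb29 also led cluster 12, Lcn5 and Defb21 cluster 1, Defb22 and Car4 cluster 26, and S100a8 and Smpx cluster 23.

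Beta-defensins (1.77, percentile 100), Kazal inhibitors (0.65, percentile 99.6) and sperm transcripts (1.58, percentile 99.8) had medians above 0 for corpus over cauda, and Spink11 stood at 1449 against 35.8 CPM. In the cauda, cholesterol synthesis was higher for 16 of 18 genes (-0.72, percentile 0.02; Msmo1 150 against 99.4 CPM), and glycolysis for 13 of 18 (-0.50, percentile 0.47). Segment transcription factors were higher in the cauda for 11 of 17 (-1.10, percentile 0), and ion and water channels for 7 of 11 (-0.58, percentile 0.32). The interferon response (-0.63, percentile 0.31), innate defence (-1.30, percentile 0), extracellular matrix (-2.62, percentile 0) and complement (-2.01, percentile 0) lay below 0, and for the matrix and complement lists RNA of fibroblast-like and macrophage-like cells, in which both sums were higher in the cauda as well, is not excluded. So did dissociation stress, immediate early and heat shock genes that tissue digestion can induce, with 21 of 25 members higher in the cauda (-0.65, percentile 0) and Jun at 1376 CPM in the cauda and 1083 CPM in the corpus.

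The mitochondrially encoded share of UMIs in the principal-marker clusters, ribosomal RNA of the organelle included, was 4.599% in the caput, 16.01% in the corpus and 12.99% in the cauda, and the medians over cells were 4.61%, 16.3% and 15.3%. The genes for proteins of the respiratory chain encoded there summed to 15644, 53595 and 40637 CPM, with all 9 measured members higher in the corpus than in the caput (-1.83, percentile 0.03). For example, mt-Cytb stood at 4009, 12721 and 8310.3 CPM. In clear-like cells, which are rich in mitochondria, the share was 12.7%, 19.9% and 19.6%, in basal-like cells 6.58%, 8.93% and 6.54%, and in macrophage-like cells 6.05%, 12.7% and 7.63%. The corpus exceeded the caput in principal-marker clusters in each alternative run, while at Leiden resolution 0.5 the cauda, at 17.1%, exceeded the corpus, at 15.97%. Ribosomal protein genes took 9.48%, 11.04% and 12.2% of principal-marker UMIs.

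**Figure D4:**
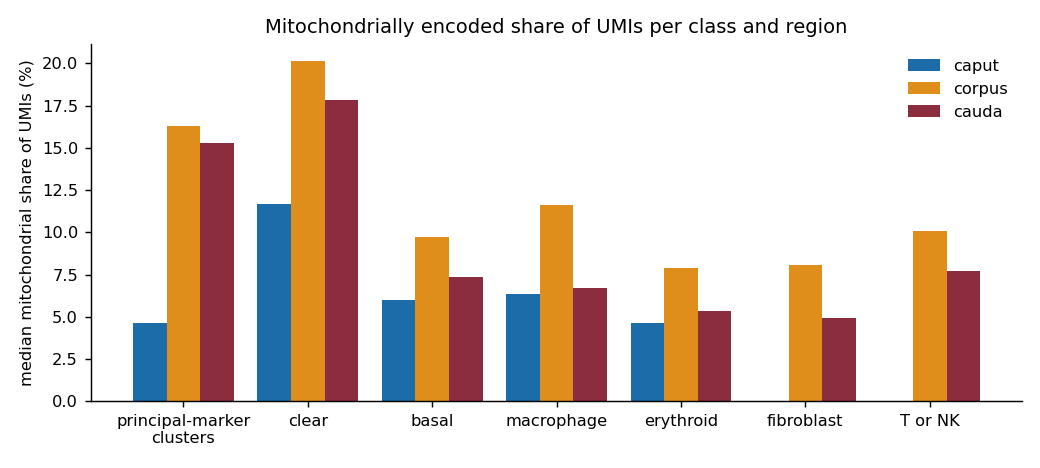
Median over cells of the mitochondrially encoded share of UMIs, in percent, per region. Principal-marker clusters and clear-like, basal-like, macrophage-like, erythroid-like, fibroblast-like and T or NK-like cells are drawn where a region held at least 50 cells. The median in principal-marker clusters was 4.61% in the caput and 16.3% in the corpus.

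Principal-marker cells had medians of 2333, 970 and 949 detected genes in caput, corpus and cauda. Thinned to 1000 UMIs per cell, the medians were 554, 534 and 533, with 8, 52 and 169 shallower cells left out.

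Clear-like cells were compared in cluster 7 for the caput, cluster 28 for the corpus and cluster 24 with 2 cells of cluster 28 for the cauda. The genes of the inhibitors of DNA binding, which hold back differentiation factors, were higher in the cauda. Id4 was 92.7-fold higher in cauda than in caput clear-like cells (50.8 to 189) and 27.99-fold higher than in corpus ones (19.1 to 42.2), at 401 CPM, and Id3 26.8-fold (20.7 to 35.1) and 20.98-fold higher (16.3 to 27.2). Id3, at 728 CPM in cauda clear-like and 711 CPM in all other cauda cells, was not particular to the class. Id2, at 1341 CPM in the cauda, was 13.1-fold and 8.404-fold higher, Id1 10.9-fold and 20.3-fold, and S100a1 7.81-fold higher than in the corpus. Id2 and Id1 were also widespread, at 1025 and 173 CPM in all other cauda cells against 1341 and 263 CPM in clear-like cells. Id4 stood at 55.6 CPM in all other cauda cells. The caput was higher for Iapp, which encodes amylin, at 171 CPM (33.6-fold over corpus, 18.6 to 67.9; at least 30.4-fold over cauda, with no cauda UMI), for the matrix gene Npnt (13.4-fold over corpus) and for the growth factor gene Wnt10a (18.5-fold over corpus). Clec2l, with no corpus UMI, was at least 33.8-fold higher in the caput than in the corpus (lower limit of the interval 27.03). Wfdc18 was 21.1-fold higher in the caput than in the corpus, at 48.8 CPM against 45.1 CPM in all other caput cells. Compared with the cauda, the caput was higher for Clca3a2 (26.6-fold), Rassf4 (22.6-fold), Prss23 (22.1-fold) and Col27a1, with 1 cauda UMI (21.6-fold, 3.79 to 862). The corpus was higher than the caput for Aldh3a1 (8.697-fold), Tmem158 (5.46-fold) and Dpp4 (4.44-fold), and higher than the cauda for Clca3a2 (19.8-fold), Tmem213 (9.27-fold) and Apoc1 (8.09-fold), and for Aldh3a1, with no cauda UMI (at least 9.12-fold), and the basal marker Krt5, with no cauda UMI (at least 10.3-fold), which at 57.8 CPM stood near the 57.7 CPM of all other corpus cells. Apoc1, at 75.9 CPM in corpus clear-like and 66.2 CPM in all other corpus cells, was likewise hardly particular to the class. Aldh3a1 stood at 51.4 CPM in corpus clear-like and 344 CPM in corpus basal-like cells. The predicted microRNA gene Gm23935 was 12.9-fold higher in the cauda than in the caput. Npnt also led cluster 7 and Id4 cluster 24, and the cauda held 97 of these cells. Their share of the cauda, 2.03%, fell to 0.0418% with 4000 variable genes and 50 components. It fell in a like way with shared barcodes left out and at Leiden resolution 2.0. All ratios of cauda clear-like cells therefore rest on a group that other clusterings did not always keep.

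Basal-like cells were compared in cluster 5 for the caput and cluster 25 for the corpus and cauda, with 1 cell of cluster 5 in each of these. As in clear-like cells, Id3 was higher in the cauda, 23.2-fold over the caput (19.3 to 28.1) and 13.2-fold over the corpus (10.1 to 17.5), Id1 5.22-fold and 10.1-fold, and Id4 8.31-fold and 5.47-fold. Id3 stood at 843 CPM in cauda basal-like and 709 CPM in all other cauda cells. Gstp1 was 4.72-fold and the long RNA gene Gm26809 5.15-fold higher in the cauda than in the caput, and the matrix proteoglycan gene Fmod 5.15-fold higher than in the corpus. The corpus was higher for genes of the dividing cell: Ube2c 11.2-fold over caput and, with 1 cauda UMI, 51.6-fold over cauda (9.08 to 2057), Pclaf 8.06-fold and, with 1 cauda UMI, 49.3-fold (8.67 to 1966), and Prc1 4.44-fold and 6.85-fold. Lgals7 was 4.25-fold higher in the corpus than in the caput, and Aldh3a1 26.3-fold and the cell cycle inhibitor gene Cdkn1a 5.88-fold higher than in the cauda. In the caput, the amino acid transporter gene Slc38a5 was 104-fold higher than in the cauda (50.3 to 258), and Wfdc18, with no cauda UMI, at least 28.8-fold higher. Slc38a5, at 1585 CPM in caput basal-like and 1553 CPM in all other caput cells, was not particular to the class. Wfdc18 was carried by a group of 167 cells, at 1366 CPM, in which the principal cell gene Gpx5 stood at 23335 CPM, so it is not read as expression by basal cells. Ccdc153, Ccdc39, Tmem212, Fam183b and Tm4sf4 were named as higher in caput than in corpus, and Cfap126, Enkur and Ccdc153 as higher than in cauda, with Ccdc153 at least 55.6-fold and at least 25.4-fold higher. Most of these are genes of motile cilia, and without the 102 ciliated-like cells Ccdc153 stood at 5.18 CPM, at least 1.73-fold the corpus level (lower limit of the interval 1.28), Ccdc39 at a ratio of 2.59 (0.369 to 113) and Fam183b at 1.69 (0.382 to 15.4). Over the cauda, Ccdc153, with no cauda UMI, then stood at a ratio of 0.79, Cfap126 at 2.37 (0.379 to 98.2) and Enkur at 2.49 (0.4 to 103). No direction over the cauda was left for these genes. Without the ciliated-like cells Id3 was 21.6-fold higher in the cauda than in the caput, while Lgals7, at 3.696-fold, no longer passed the size rule. Lgals7 and Aldh3a1 also led cluster 25, and the cauda held 75 of these cells.

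**Figure D5:**
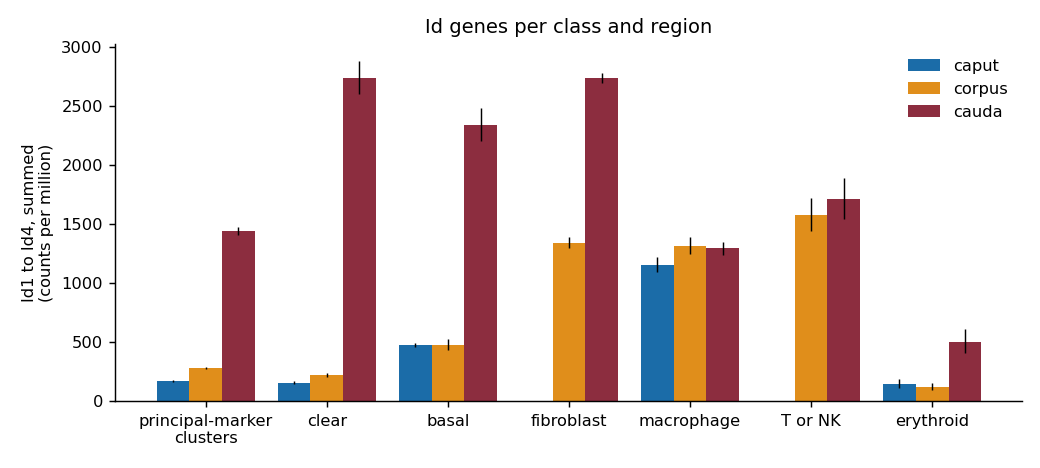
Summed CPM of Id1, Id2, Id3 and Id4 per region, with exact 95% Poisson intervals (counting error only). Principal-marker clusters and clear-like, basal-like, fibroblast-like, macrophage-like, T or NK-like and erythroid-like cells are drawn where a region held at least 50 cells. In clear-like cells Id2, a part of the sum, lay at 103 in the caput, 159.6 in the corpus and 1341 in the cauda.

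Macrophage-like cells lay in cluster 10 for the caput, with 1 cell of cluster 17, and cluster 17 for the corpus and cauda, so the caput comparisons set 2 clusters against each other. The scavenger receptor gene Cd163, with 1 caput UMI, was 181-fold higher in the corpus (31.97 to 7207) and 386-fold higher in the cauda (68.9 to 15263), the hyaluronan receptor gene Lyve1 81.6-fold (39.3 to 204) and 169-fold (82.1 to 422), and Retnia, as the symbol is written in the matrix, 621-fold (242 to 2282) and 1256-fold (490.2 to 4610.1). The chemokine gene Ccl8 was 70.7-fold and the lectin gene Clec10a 68.7-fold higher in the corpus, and in the cauda the complement gene C4b, with 1 caput UMI, was 303-fold higher (54.1 to 12009) and Cd209f, with no caput UMI, at least 154-fold. The genes with the largest ratios in the caput were Lcn9, Rnase10, Defb25 and Cst8 over the corpus and Lcn9, Cst8, Defb48 and Lcn8 over the cauda, with the clone-named RP23-319C8.1 and RP23-250M11.8. They are secretory genes of principal cells, and Lcn9 stood at 12020.5 CPM in caput macrophage-like cells against 13698 CPM in caput principal-marker clusters. Over 7 genes of secreted families among the most abundant of caput principal-marker clusters, macrophage-like cells held a median of 82.3% of the principal level, against 16.2% in basal-like and 35.2% in erythroid-like cells. These levels are of UMIs summed over cells. The median share per cell, given further below, was lower in macrophage-like than in erythroid-like cells. Between cauda and corpus, both in cluster 17, the mast cell genes Tpsb2, with 1 corpus UMI (60.8-fold, 10.7 to 2421), Cpa3, with 2 corpus UMIs (46.3-fold, 12.6 to 385), and Cma1 (36.8-fold, 14.2 to 136) were higher in the cauda, as were Prg4, with 2 corpus UMIs (31.2-fold, 8.44 to 261), and the smooth muscle actin gene Acta2 (8.85-fold), at 232 CPM against 191 CPM in all other cauda cells. Tpsb2, Cpa3 and Cma1 are listed mast cell markers, so mast cells within cluster 17 are not excluded. They are not read as genes expressed by macrophages. Fabp4 was 5.21-fold higher in the corpus. In this class the antigen presentation list had medians of -0.32 for caput over corpus (percentile 13.9), -0.54 for caput over cauda (percentile 13.98) and -0.27 for corpus over cauda (percentile 27.5), and the complement list -0.85 (percentile 0.19), -2.22 (percentile 0) and -0.95 (percentile 0). Its matrix genes had medians of -0.71, -2.65 and -2.20, and its contractile genes 1.28, -1.55 and -2.96. The contractile list summed to 1969.6 CPM in caput and 914 CPM in cauda macrophage-like cells, against the direction of its median, and to 2009.5 CPM in caput principal-marker clusters, so RNA of other cells is not excluded for these 2 lists. Cd163, Ccl8 and Clec10a also led cluster 17.

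Fibroblast-like cells of corpus and cauda shared clusters 19 and 20. The chemokine gene Cxcl13, which attracts B cells, was 23.9-fold higher in the corpus (17.6 to 33.1), at 187 against 7.84 CPM, as were Hsd11b1, which activates glucocorticoids (4.94-fold, 4.03 to 6.07), and the body axis gene Hoxc8 (5.35-fold, 4.24 to 6.798). In the cauda, Hoxa11, with 3 corpus UMIs, was 47.5-fold higher (16.1 to 231) and Hoxd10 10.5-fold (3.99 to 39.4). Myoc, with no corpus UMI, was at least 27.4-fold higher in the cauda, the growth factor receptor gene Kdr 13.8-fold (7.63 to 27.9) and Tagap 8.04-fold (4.71 to 14.9). Matrix genes were higher in the cauda for 21 of 24 members (-0.73, percentile 0), and contractile genes in the corpus for 8 of 14 (0.46, percentile 99.95). The complement and antigen presentation lists had medians of -0.15 (percentile 17.1) and -0.35 (percentile 2.08).

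T or NK-like cells of corpus and cauda shared cluster 16. The chemokine gene Ccl7 was 12.6-fold higher in the cauda (7.62 to 22.2), the mast cell protease gene Mcpt4 4.42-fold (3.48 to 5.65) and Tnfaip3, a brake on inflammatory signalling, 4.19-fold (2.89 to 6.19), while Car2 was 18.2-fold higher in the corpus (8.17 to 50.3). Mcpt4, a listed mast cell marker, stood at 1275 CPM in cauda T or NK-like cells and 15.2 CPM in all other cauda cells. Mast cells within cluster 16 are not excluded, and Mcpt4 is not read as expression by T or NK cells. In erythroid-like cells, in cluster 4 for the caput and cluster 21 for the corpus, Gm10800 was 4.07-fold higher in the corpus (2.57 to 6.74).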

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

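The tests of the 3 patterns in this part were chosen only after the result was seen, and their thresholds were set after part of the values had been seen. Cells of the 6 clusters counted with no class were used in no comparison between regions: 41 cells of cluster 2 (smooth muscle and pericyte markers), 370 of cluster 9 (smooth muscle and fibroblast markers), 385 of cluster 13 (macrophage markers with the dendritic marker Cd209a), 23 of cluster 14 (ciliated and germ cell markers), 1531 of cluster 22 and 133 of cluster 27 (fibroblast and macrophage markers). Cluster 22, nearly all from the cauda, was led by mt-Rnr2 and held matrix genes such as Col1a1 among its leading genes, with a median of 965 UMIs per cell and a median mitochondrial share of 21.9%. A further 23 barcodes were listed in more than 1 library.

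The mitochondrial share was higher in corpus than in caput principal-marker clusters. In cells of 2000 to 8000 UMIs the ratio of the medians was 2.57, against 1.41 to 1.73 in basal-like, clear-like, erythroid-like and macrophage-like cells, which is 1.48 times the highest of these and argues against a difference common to all cells of the libraries as the whole cause. At matched depth the ratio was 2.23 in cells of 2000 to 4000 UMIs and 2.76 in cells of 4000 to 8000 UMIs, which argues against shallower corpus cells. The ratio lay above 1 in each of these classes, so part of it may belong to the library. Damage that struck principal cells more than others, and a difference between the regions of the duct, stay open and were not tested.

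Summed over cells, caput macrophage-like cells held transcripts of secreted families at a higher level than other caput classes without principal markers, while the median share per cell was 3.01%, against 3.28% in erythroid-like, 1.84% in basal-like, 1.81% in clear-like and 1.405% in endothelial-like cells. The share of secreted families in the deep part of the macrophage-like cells was 2.31 times that in the shallow part, against 0.378 in basal-like, 0.7698 in clear-like, 0.615 in endothelial-like and 1.29 in erythroid-like cells, and 1.798 in the macrophage-like cells over the 10 most abundant genes with Itm2b and Tmsb4x, which argues against free RNA in equal amount per cell. The macrophage-like cells with the highest share over those 10 genes had 2.46 times the median UMIs of the others and a median Scrublet score of 0.0758 against 0.0226, as was written down for principal cells captured together with macrophages or taken up by them, but the first is not separate from the result on depth and no cell passed the threshold of the score. Both explanations therefore stay open. The genes of secreted proteins named for caput macrophage-like cells are not read as expression by macrophages.

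The summed CPM of Id1, Id2, Id3 and Id4 was higher in cauda than in corpus cells of several classes, with a ratio of 12.3 in clear-like, 5.11 in principal-marker, 4.88 in basal-like, 3.99 in erythroid-like and 2.04 in fibroblast-like cells, but 0.984 in macrophage-like and 1.08 in T or NK-like cells. In cauda erythroid-like cells it was 18.4% of that in clear-like, 21.5% of that in basal-like and 34.8% of that in principal-marker cells, which argues against free RNA of the cauda library as the cause in clear-like cells, while part of the rise in the others may be free RNA. For Id2 the lowest ratio among the classes other than clear-like, basal-like and erythroid-like cells was 0.867, in macrophage-like cells, which argues against a rise common to all classes. For Id1, Id3 and Id4 the lowest ratio was 2.02 (Id3 in fibroblast-like cells, 1.91 to 2.14), so a rise common to all classes of the cauda library is a candidate explanation for part of the difference in these 3 genes, although Id4 in T or NK-like cells rested on 4 cauda and 2 corpus UMIs (2.84, 0.407 to 31.4), Id1 there on 12 and 2 UMIs, and Id4 in macrophage-like cells on 31 and 7 UMIs (2.42, 1.05 to 6.52). Id genes respond quickly to signals, and the dissociation stress list, which was run only in principal-marker clusters, was also higher in the cauda there, so a response to tissue handling stays open, as does a difference between the regions, which was not tested.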

How the results depend on the processing

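The alternatives that left out the highest Scrublet scores, cells under 1000 UMIs, shared barcodes or cluster 22, that thinned the sums, that kept to cells of 2000 to 8000 UMIs, and that split clusters 5 and 9 were chosen after the data were seen. The other alternatives were set in advance. No paired analysis was possible because each region has 1 library, and leaving out a replicate could not be run for the same reason. Keeping called doublets changed nothing because none was called. Ratios of named genes and list medians were rerun in principal-marker clusters only, under other scalings and with the deepest cells left out. None of these that was given a direction changed sign there. The clustering and filter alternatives gave no ratio of a single gene. Ratios in the other classes were run under no alternative, except in basal-like cells without the ciliated-like group. There, several genes of motile cilia lost their direction. At Leiden resolution 0.5 the order of corpus and cauda turned for the mitochondrial share and for the numbers of genes past the size rule, as given below. Of 165 shares 96 stayed within their interval, of 33 mitochondrial shares 2, and of 114 numbers of genes past the size rule 95 stayed within 1.5 times.

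The values that moved follow, in percent of each library's cells for shares and of UMIs in principal-marker clusters for mitochondrial shares. The cause of these moves was not tested, except that leaving cells out of a denominator raises the other shares by construction. With a minimum of 500 genes per cell, shares were caput basal 9.58% and fibroblast 5.45%, corpus clear 11.7% and fibroblast 13.3%, cauda principal 19.4%, clear 2.93%, basal 2.09%, fibroblast 48.8% and macrophage 12.4%, and mitochondrial shares corpus 14.7% and cauda 13.2%. With cells over 20% mitochondrial UMIs left out, shares were caput clear 11.6%, basal 9.66% and fibroblast 5.93%, corpus principal 44.8%, clear 7.41%, basal 4.49%, fibroblast 16.1% and macrophage 6.51%, cauda principal 15.5%, clear 1.58%, basal 2.14%, fibroblast 53.9% and macrophage 12.2%, and mitochondrial shares caput 4.501%, corpus 10.98% and cauda 10.2%. With cells under 1000 UMIs left out, shares were caput basal 9.45% and fibroblast 5.71%, cauda principal 14.4%, clear 2.73%, fibroblast 33.2% and macrophage 11.1%, and mitochondrial shares caput 4.59%, corpus 15.8% and cauda 12.7%. With the 6% highest Scrublet scores left out, shares were caput basal 10.3% and fibroblast 4.902%, corpus clear 9.09%, cauda principal 16.2%, clear 2.94% and fibroblast 26.3%, and mitochondrial shares caput 4.56%, corpus 15.2% and cauda 13.8%. With shared barcodes left out, shares were caput fibroblast 5.75%, cauda principal 15.3% and clear 0.04199%, and mitochondrial shares caput 4.56%, corpus 16.05% and cauda 12.6%. With random seed 1, shares were caput basal 9.25% and fibroblast 5.73%, cauda principal 19.2%, clear 1.63% and fibroblast 26.4%, and mitochondrial shares caput 4.57%, corpus 16.05% and cauda 13.7%. With Leiden resolution 0.5, shares were caput principal 52.3% and basal 12.7%, corpus macrophage 9.19%, cauda principal 49.9% and macrophage 13.04%, and mitochondrial shares caput 4.65%, corpus 15.97% and cauda 17.1%. With Leiden resolution 2.0, shares were caput principal 48.6%, basal 9.25% and fibroblast 5.77%, corpus principal 37.1%, cauda clear 0.0836% and fibroblast 50.1%, and mitochondrial shares caput 4.56%, corpus 16.6% and cauda 13.2%. With 4000 variable genes and 50 components, shares were caput basal 11.8% and fibroblast 5.69%, cauda principal 19.5% and clear 0.0418%, and mitochondrial shares caput 4.58% and cauda 13.4%. With each library clustered on its own, shares were caput principal 47.9%, basal 8.79% and fibroblast 5.83%, corpus principal 30.8%, cauda clear 3.197%, fibroblast 27.8% and macrophage 16.99%, and mitochondrial shares caput 4.64%, corpus 14.1% and cauda 13.5%. With cluster 22 left out of the denominator, shares were cauda principal 25.9%, clear 2.97%, basal 2.296%, fibroblast 36.6% and macrophage 13.5%. In cells of 2000 to 8000 UMIs alone, mitochondrial shares were caput 6.38%, corpus 18.97% and cauda 17.7%.

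For genes past the size rule in principal-marker clusters, the comparison follows the numbers in brackets. Looser or stricter thresholds change these numbers by construction, and for the others the cause was not tested. With Leiden resolution 0.5, the numbers were 338 higher in cauda (corpus against cauda). With Leiden resolution 2.0, the numbers were 163 higher in corpus (corpus against cauda). With at least 30 UMIs, the numbers were 782 higher in corpus (caput against corpus), 727 higher in cauda (caput against cauda), 414 higher in corpus and 265 higher in cauda (corpus against cauda). With at least 300 UMIs, the numbers were 254 higher in corpus (caput against corpus), 542 higher in caput and 197 higher in cauda (caput against cauda), 127 higher in corpus and 60 higher in cauda (corpus against cauda). With a fold of at least 2, the numbers were 1132 higher in caput and 838 higher in corpus (caput against corpus), 826 higher in cauda (caput against cauda), 318 higher in cauda (corpus against cauda). With sums thinned to equal totals, the numbers were 376 higher in caput and 282 higher in corpus (caput against corpus), 406 higher in caput (caput against cauda), 150 higher in corpus (corpus against cauda). Median genes per cell were, with cells not thinned 2333 (caput), 970 (corpus) and 949 (cauda) and, with cells thinned to 500 UMIs 319.9 (caput), 312 (corpus) and 309 (cauda).

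Of 505 list medians under other scalings, 424 stayed within their range and 81 moved. In at least 1 scaling, 13 medians of 11 lists changed sign. Those for caput over corpus were given without a direction, and those for the other comparisons were not given. Of 300 ratios of named genes 12 moved, each with the mean of each cell's CPM, by up to 2.98 log2 (Spint5, corpus over cauda), with the direction kept. They were those of Cst11, Spag11b, Lcn9, RP23-319C8.1, RP23-250M11.8, RP23-146D13.2 and RP23-138I21.4 for caput over corpus, of Ly6g5c, Cst8 and RP23-146D13.2 for caput over cauda, and of Spint4 and Spint5 for corpus over cauda. List medians moved by up to 1.01 log2. Leaving out mitochondrially encoded genes from the total shifted the median log2 ratio of all genes by -0.18 for caput over corpus and -0.13 for caput over cauda, and for caput over cauda TMM factors shifted it by 0.13 and median-of-ratios factors by 0.11.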

Other observations

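Of the tests in this part, the one on cell cycle genes was chosen only after the result was seen, and the one on Hox genes was written down before its values were seen, with the 3 genes already seen left out. Cluster 11, of 55 caput cells, was led by Cenpf, Hmmr and Cdc20, genes of dividing cells, and carried principal markers. Dividing principal cells might from this have been thought a feature of the caput. Among principal-marker cells thinned to 2000 UMIs, at least 2 UMIs of cycle genes were found in 9.43% of caput, 10.8% of corpus and 2.37% of cauda cells. For this, 28, 1030 and 381 shallower cells were left out. The caput share was 0.8701 times the higher of the others. Over all principal-marker cells, shallow ones included, the cycle genes summed to 307 CPM in the caput (301 to 314), 365 CPM in the corpus (354 to 375) and 57.7 CPM in the cauda. This argues against a higher level of these genes in the caput than in both other regions. At such levels a cell that is not dividing can also hold 2 of these UMIs, so the shares do not count dividing cells. Whether dividing principal cells are a feature of the caput therefore stays open. Without thinning the shares were 19.8%, 14.7% and 5.56%, where the deeper caput cells had more UMIs in which to find these genes. In basal-like cells, where Ube2c and Pclaf were named as higher in the corpus, the share was 4.41% in the caput (2.996 to 6.24), 10.8% in the corpus (6.31 to 16.96) and 0% in the cauda (up to 7.11%), with 30 of 680, 16 of 148 and 0 of 50 cells.

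Among Hox genes, which mark position along the body axis, Hoxc8 was higher in corpus and Hoxa11 and Hoxd10 in cauda fibroblast-like cells, and a candidate explanation was a general order along the duct. With these 3 genes left out, the median log2 ratio of cauda over corpus was -0.04 for paralogue groups 9 to 13 and -0.73 for groups 1 to 8. The difference of 0.683 lay in the proposed direction but the first median was not above 0, and the question stays open.

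Gpx5 and Gpx3, which encode glutathione peroxidases, differed in opposite directions between the caput and the other regions in principal-marker clusters, with Gpx5 at 40160.3, 19.1 and 116 CPM and Gpx3 at 179, 6046 and 8118 CPM in caput, corpus and cauda. The other abundant members of their list, Prdx1 and Txn1, stood at 1364 and 1023 CPM in the caput and 1239 and 747 CPM in the corpus.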
